A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

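Gene expression was measured on 8 Agilent 2-colour oligonucleotide arrays, 1 for each sampled time of 16, 17, 19, 20, 21, 22, 23 and 24 h. The yeast was S288C, the laboratory strain of Saccharomyces cerevisiae behind the reference genome, grown as a batch culture in minimal medium. Per the labels, each array carried RNA of exponentially growing cells in Cy5 (red) and RNA of cells aged 64 h in Cy3 (green). The 64 h RNA was the common reference on every array and the dyes were never swapped. Nothing in the labels says that the samples came from separate cultures, so p-values measure only the scatter between these arrays, which may be technical.

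The deposited scanner files hold spot intensity values per channel, made with Agilent Feature Extraction 10.5.1.1 per the file headers; that software is also named in the submitters' processing notes. Per the file headers, the design was annotated on the sacCer2 build. The intensity columns used here are the median signal and the median local background of each spot. The same deposited files give a log10 ratio of red over green, which the scanner software had corrected for background and for dye. Other columns mark, per spot and channel, whether a signal was well above background, saturated or an outlier. The authors' value table holds 5609 genes on a log2 scale. From its values, each gene was centred on 0 over the 8 columns and the direction was that of Cy5 over Cy3. How its values were normalized is not given in the sources used here. Its column medians lay between -0.0124 and 0.0147.

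The background was corrected with normexp (offset 50) on the median signals, since the files held no mean signals, which the design chosen beforehand had named. Ratios were normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier spots and controls were then left out, and the 2 spots of a probe were averaged. Where a gene had several probes (29 genes), the one with the highest mean log intensity was used; no such gene had probes more than 1 apart in mean log2 ratio. Of 6225 systematic names, 5737 matched a locus tag of the reference table (assembly R64), which gave the symbols. The other 488 kept the name in the files. The builds differ, so no coordinates are given. A gene was tested when its spots were well above background on at least 4 arrays in Cy5 or at least 4 in Cy3, which left 5650 genes.

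Straight lines of the log2 ratio on centred time were fitted with lmFit and eBayes. The slope answers whether a gene changed over the hours, and the intercept tests the mean log2 ratio against 0. The intercept leaves out the spread of the 64 h cells, which were not sampled again, and holds any dye bias. A squared time term tested for curved courses. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The 35 gene lists were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Their adjusted p-values are over the 35 lists.

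Genes are named by a rule also written before the data were examined. For the mean ratio and the slope, it takes the 7 largest coefficients in each direction among genes past the threshold, the 2 members with the smallest p in each of up to 8 called lists, and 14 fixed genes. For curvature it takes the 5 smallest p-values. For the mean ratio, a channel saturated on all 8 arrays, or never well above background, gives only a bound, written as at least N-fold, and no bound where the other channel was saturated on any array. Genes saturated in Cy5 on all 8 arrays are given no slope. Such a bound sets the mean of the bright channel against the dim one after loess and Aquantile normalization, and is open to dye bias.

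Arrays lay on 2 slides. Slide 1 held the arrays recorded at 16, 19, 22, 23 and 24 h, and slide 2 those recorded at 17, 20 and 21 h. Each slide was scanned in its own session, so slide and scan are the same batch here. Between 84.1% and 91.6% of the 12512 gene spots per array were well above background in Cy5, and between 89.5% and 91.1% in Cy3. The correlation between the 2 spots of a probe, across genes, was 0.984 to 0.990 within an array. The number of arrays limits the precision.

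The scanner files recorded for 20 h and 24 h do not match the authors' table columns of the same samples, and each matches the column of the other. The main fits keep every file at the sample it is recorded for. After this mismatch was seen, 2 further fits were added beside each time result: one on the 6 arrays whose time is not in dispute, and one with the 20 h and 24 h files exchanged. The rule for named genes was applied to those fits as well.

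The fits were tested on simulated data over 5650 genes with 200 changed slopes. With the residual spread of the arrays as recorded, 55 of 100 genes with a slope of 0.1 per h and 95 of 100 with 0.2 per h were recovered. With the spread of the 6 arrays, 78 of 100 and 98 of 100 were recovered. With the spread of the exchanged fit, the numbers were also 78 of 100 and 98 of 100. A list shifted in a simulation was called, and 0 unshifted lists were. The simulated genes varied independently of each other. On the arrays, the correlation estimated within lists for the mean ratio ranged from -0.02 (heat shock factor chaperones) to 0.88 (low-affinity glucose transport). The simulation therefore cannot tell how often camera at the preset correlation calls unshifted lists whose genes vary together. Alternatives covered the background correction, the normalization, the scanner's ratios, the authors' table, the filter on dim probes, the eBayes options, the slide as a block and each slide alone. They also covered leaving out each array, later against earlier arrays, each channel alone and the camera correlation.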

Results

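The series followed yeast cells growing in minimal medium over 8 h and compared them with cells of the same strain aged 64 h. The 8 arrays form 1 group of exponentially growing cells, with 1 array at each of 16, 17, 19, 20, 21, 22, 23 and 24 h, so no time point has a replicate. On each array, Cy5 carried the growing cells and Cy3 the 64 h cells. A positive log2 ratio therefore means a higher level in the growing cells. The median Cy5 signal ranged from 992.5 to 1674 and the median Cy3 signal from 1386 to 2032. The array recorded at 16 h had the fewest spots well above background in Cy5, 10521 of 12512. Log2 ratios of different arrays correlated with each other across genes at 0.816 or higher. Genes are not independent replicates in these correlations.

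The first comparison asked which genes differed between growing cells and cells aged 64 h. Relative to other genes, growing cells held more mRNA for glucose uptake and for making ribosomes. They held relatively less for respiration, gluconeogenesis and stress protection. These are gene lists called by camera at the preset correlation. With an estimated correlation 0 of the 35 lists were called, the smallest adjusted p being 0.12. That correlation was estimated about the line as recorded, which includes the 2 arrays whose times are in dispute. For ribosome biogenesis it was 0.86 there, 0.25 on the 6 undisputed arrays and 0.70 with the files exchanged. For thiamine and vitamin B6 genes it was 0.04, 0.03 and -0.01. The mean ratio was not tested with the correlations of the other 2 fits. With limma, 2278 genes were higher in growing cells and 2408 were lower, among 5650 tested. Of these, 260 were at least 2-fold higher and 578 at least 2-fold lower. Both counts set the 8 arrays against a single reference RNA and leave out the spread of 64 h cells. The majority turned with other scalings: 2530 were higher and 2219 lower with the scanner's ratios, and 2322 and 2280 with median centring. Without the arrays recorded at 20 h and 24 h, 2294 genes were higher and 2444 lower. With the slide as a block, 4861 genes were called, and within slide 1 and slide 2 alone 4677 and 2746, slide 2 having 3 arrays.

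Sugar transporter and glucose repression genes led the genes higher in growing cells. HXT2 (YMR011W), a glucose transporter, was 59.5-fold higher, with a log2 ratio of 5.90 ± 0.07 (SE, n = 8; limma adjusted p = 7.6e-12). MIG2, a repressor that acts when glucose is present, stood at 3.99 ± 0.28. HXT3, a low-affinity glucose transporter with Cy5 saturated on 3 arrays, stood at 3.93 ± 0.54. The amino acid permease genes GNP1 and DIP5 had log2 ratios of 3.74 and 3.68, and the phosphate transporter gene PHO84 had 3.46 ± 0.07. INA1 completed the 7 largest at 3.62. HXT1, another low-affinity transporter, was at 2.93 ± 0.50 (adjusted p = 0.00038), and its Cy3 spots, like those of GNP1, were well above background on 7 of the 8 arrays. All 4 genes of the low-affinity glucose transport list were higher, with a median log2 ratio of 3.52 (camera adjusted p = 0.010; adjusted p = 0.41 with an estimated correlation).

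Genes for ribosomes and their assembly were also higher in growing cells. Of 132 cytosolic ribosomal protein genes, 115 were higher, 11 were lower and 6 did not pass. The same counts held when adjusted over the list alone. Their median log2 ratio was 0.88, with RPL21A at 1.77 ± 0.06. RPL9A was at least 2.69-fold higher, its Cy5 spots being saturated on all 8 arrays. RPL3, a protein of the large subunit with Cy5 saturated on 5 of the 8 arrays, was at 0.74 ± 0.06. Among 114 ribosome biogenesis genes, 109 were higher and 0 lower, as they were when adjusted over the list alone. The median of that list was 0.72. By array, its median was 0.04 on the array recorded at 20 h and 0.55 to 0.97 on the others. EMG1 and NOP58, which act in small-subunit assembly and in rRNA modification, stood at 1.38 and 1.35. NSR1, a nucleolar protein of rRNA processing, did not pass at 0.31 ± 0.16 (adjusted p = 0.094). Purine and pyrimidine biosynthesis genes were higher in 24 of 26 cases and lower in 1, with a median of 0.60. The same numbers passed when adjusted over the list alone. IMD3, for guanine nucleotide synthesis, was 2.14-fold higher, and the lower gene was URA10, for pyrimidine synthesis, at a log2 ratio of -1.27. With an estimated correlation the adjusted p was 0.28 for ribosomal proteins, 0.43 for ribosome biogenesis and 0.38 for purines and pyrimidines.

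The largest differences lay in genes lower in growing cells. YRO2, a membrane protein related to HSP30, had a log2 ratio of -8.39 ± 0.11 and STL1, a glycerol transporter, one of -7.79 ± 0.06. Their Cy5 spots were well above background on 6 and 7 of the 8 arrays. MLS1, the malate synthase of the glyoxylate cycle, stood at -7.28 ± 0.04 (adjusted p = 3.9e-14). PCK1, the gluconeogenic PEP carboxykinase, was at least 140.1-fold lower in growing cells, HSP30 at least 89.2-fold and the hexose transporter HXT5 at least 88.7-fold. In these 3 genes the Cy3 spots were saturated on all 8 arrays. YGP1, a glycoprotein induced on starvation, stood at -6.51 ± 0.17. ADH2, which oxidises ethanol, was at -6.11 ± 0.08, with Cy3 saturated on 6 arrays.

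Lists of glucose-repressed, respiratory and stress genes were lower as groups. Of 32 glucose-repressed and gluconeogenic genes, 28 were lower and 3 higher, with a median log2 ratio of -3.80. IDP2, a cytosolic isocitrate dehydrogenase, stood at -5.59. Adjusted over the list alone, 29 were lower. Of 37 oxidative phosphorylation genes, 36 were lower and 1 higher, with a median of -1.62. The cytochrome c oxidase subunits COX12 and COX9 were at -2.06 and -2.10. In the tricarboxylic acid cycle, 19 of 21 genes were lower, with CIT3 at -2.51. CIT1, the mitochondrial citrate synthase, was saturated in Cy3 on all 8 arrays and in Cy5 on 2, so no fold is given. In the general stress response list, 57 of 61 genes were lower and 2 higher, with a median of -1.93. GRE1 and TKL2 were at -5.49 and -5.42, the small heat shock protein HSP12, saturated in Cy3 on 3 arrays, at -4.18 ± 0.37 and the catalase CTT1 at -3.60 ± 0.18. Of 21 thiamine and vitamin B6 genes, 20 were lower and 1 higher, with SNZ3 at -2.86 and SNZ2 at -2.73. The counts of these last 4 lists were the same when adjusted over the list alone. With an estimated correlation the adjusted p was 0.28 for glucose-repressed genes, 0.30 for oxidative phosphorylation, 0.41 for the tricarboxylic acid cycle, 0.41 for stress and 0.12 for thiamine and vitamin B6.

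Other fixed genes differed too. INO1, for inositol synthesis, was at -5.24 ± 0.22. The amino acid permease gene GAP1, with Cy5 saturated on 4 arrays, stood at 0.59 ± 0.09, and the G1 cyclin gene CLN2 at 0.34 ± 0.04. HXT7, a high-affinity glucose transporter, was higher by at least 1.73-fold, with Cy5 saturated on all 8 arrays. MET17, of sulfur assimilation, was saturated in both channels on all 8 arrays and has no fold. Camera called 23 of the 35 lists at the preset correlation, 10 higher and 13 lower in growing cells, and 0 with an estimated correlation. With median centring in place of loess, 17 lists were higher and 12 lower.

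**Figure D1:**
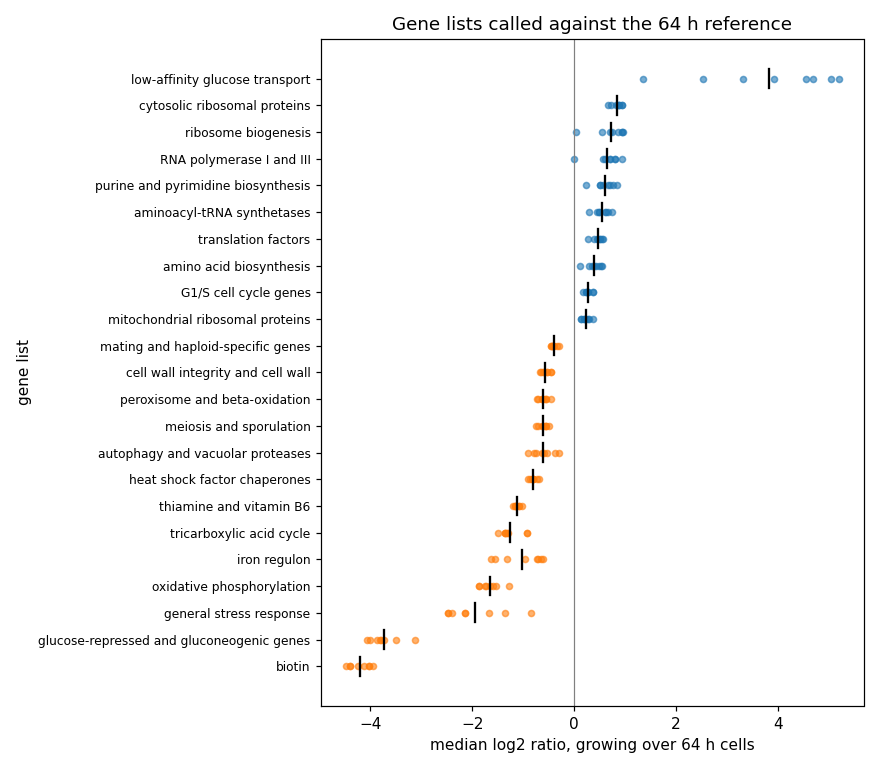
Median log2 ratio of growing over 64 h cells (horizontal axis) for each of the 23 gene lists called by camera at the preset correlation (vertical axis). Each point is 1 of the 8 arrays and the black bar is their mean. Low-affinity glucose transport lies farthest right and the biotin list farthest left, with its bar at -4.20.

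The second comparison asked which genes changed between 16 h and 24 h. For this question the recorded times of 2 arrays matter. The scanner file recorded for 20 h correlated, across genes, at -0.48 with the authors' table column for 20 h and at 0.97 with that for 24 h. The file recorded for 24 h correlated at -0.38 with its own column and at 0.92 with the column for 20 h. Each of the other 6 files matched its own column best, at 0.62 to 0.97. These values set the scanner ratios, centred within each slide, against the table. Time results are therefore given with the arrays as recorded, on the 6 arrays not in dispute, and with the 20 h and 24 h files exchanged.

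**Figure D2:**
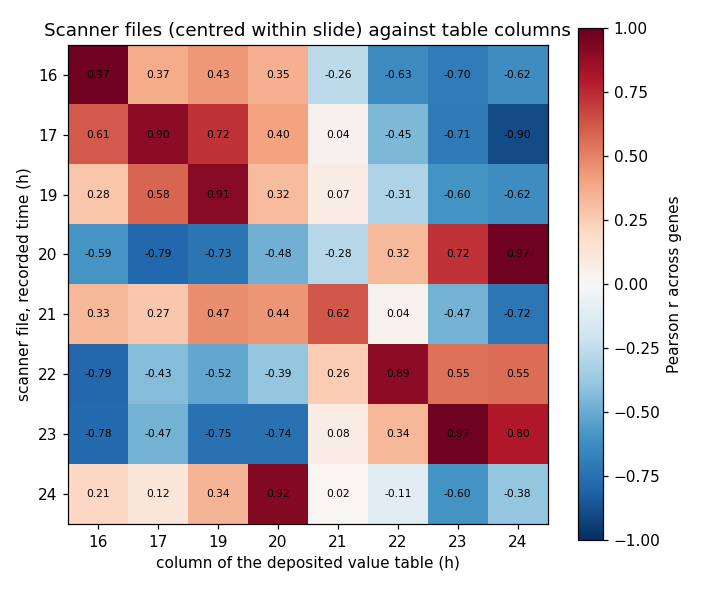
Pearson correlation across genes between each scanner file, centred within its slide (rows, by recorded time in h), and each column of the deposited value table (columns, in h). The files recorded for 20 h and 24 h have their highest values, 0.97 and 0.92, in each other's column.

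With the arrays as recorded, limma called 0 genes with a slope, and 385 had an unadjusted p under 0.05. The smallest adjusted p was 0.71, and the iron uptake genes FTR1 and FET3 had slopes of 0.18 ± 0.03 and 0.23 ± 0.05 log2 units per h, FET3 being saturated in Cy5 on 5 arrays and in Cy3 on 6. On the 6 undisputed arrays it called 473 genes, 294 rising and 179 falling. With the files exchanged it called 1079, 594 rising and 485 falling. Of the 473 genes, 462 were also called, in the same direction, in the exchanged fit. The exchanged fit holds these 6 arrays at the same times, so a large overlap was likely in advance. The 46.3 genes that independent lists would share are therefore no yardstick for it. With the slide as a block, the count stayed at 0 as recorded and became 1187 on the 6 arrays and 1707 with the files exchanged. Within slide 1 the exchanged fit called 1247 genes and within slide 2, on 3 arrays, 1 gene. As recorded, each slide alone gave 0. Leaving out the 16, 19, 22 or 23 h array reduced the 473 calls to 194, 291, 205 and 106. In the exchanged fit, leaving out the 16 h array gave 680, the 23 h array 715 and the array recorded at 20 h 563.

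In both added fits, some genes for iron uptake and stress protection rose, and 2 of the 4 low-affinity glucose transport genes, HXT1 and HXT3, fell. With an estimated correlation that transport list had adjusted p-values of 0.23 on the 6 arrays and 0.18 with the files exchanged. FIT2 and FIT3, cell wall mannoproteins that help take up siderophore iron, rose by 0.64 ± 0.06 and 0.57 ± 0.06 log2 units per h (SE, n = 6 arrays; limma adjusted p = 0.0011 and 0.0014). The siderophore transporters SIT1 and ARN1 rose by 0.39 and 0.36 per h. TIS11, which degrades mRNAs in low iron, rose by 0.39 per h, with Cy5 well above background on 7 of 8 arrays. HSP12 rose by 0.41 ± 0.05 and the lactate transporter JEN1 by 0.37 ± 0.05. Cy3 was saturated throughout for JEN1, so its slope is uncertain as a rate. HXT1 fell by 0.56 ± 0.06 and HXT3, with Cy5 saturated on 3 of the 8 arrays, fell by 0.45 ± 0.07 per h. The repressor gene MIG3 fell by 0.29 and the permease gene GNP1 fell by 0.23. SNO1 and SNZ1, paired genes of vitamin B6 metabolism, fell by 0.25 and fell by 0.22, and NCE103, the carbonic anhydrase, fell by 0.22. With the files exchanged, the slopes of FIT2, HSP12 and HXT1 were 0.63, 0.47 and -0.61. There GPH1 and GAC1, of glycogen metabolism, rose by 0.39 and 0.40, and the malic enzyme gene MAE1 and MIG2 fell by 0.23 and fell by 0.30. As recorded, none of these genes passed; HSP12 had a slope of 0.26 ± 0.14 (adjusted p = 0.72) and HXT1 one of -0.32 ± 0.19.

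By list, 32 of 61 general stress response genes rose on the 6 arrays and 0 fell, with a median slope of 0.11 per h. PHM7 and DDR2 rose by 0.25 and 0.22, DDR2 being saturated in Cy3 on 3 arrays, and CTT1 by 0.13 ± 0.02. Of 26 iron regulon genes, 19 rose. Of 114 ribosome biogenesis genes, 28 fell and 0 rose, with NOP7 and PWP1 at -0.11 and -0.12 per h. Adjusted over the list alone, 45 stress genes and 19 iron genes rose and 66 ribosome biogenesis genes fell. With the files exchanged, 45 stress genes and 18 iron genes rose and 78 ribosome biogenesis genes fell. As recorded, 0 members of these 3 lists passed over all genes, and 9 iron genes passed adjusted over the list alone. On the 6 arrays, 0 of 132 ribosomal protein genes passed, and 11 fell with the files exchanged. The 132 include genes saturated in Cy5, such as RPL9A on all 8 arrays, in which a fall may not show. RPL3, saturated in Cy5 on some arrays, had a slope of -0.06 ± 0.02 on the 6 arrays (adjusted p = 0.053). With the files exchanged it fell with an adjusted p of 0.0067. As a list, ribosomal protein genes were called downward at the preset correlation in each of the 3 fits. On the 6 arrays 109 of 132 slopes were below 0 (camera adjusted p = 6.8e-06, and 0.22 with an estimated correlation). Among these 3 fits, NSR1 passed only with the files exchanged, at -0.14 ± 0.04.

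Some respiratory genes rose on the 6 arrays and some biosynthetic genes fell. In the tricarboxylic acid cycle 8 of 21 genes rose, with SDH1 and SDH3 at 0.22 and 0.18 per h; the Cy3 spots of SDH1 were saturated on all arrays and those of SDH3 on 7. CIT1 is among the 8, but its slope of 0.12 is not a measured rate, with Cy3 saturated on all arrays and Cy5 on 2. In oxidative phosphorylation 5 of 37 rose, among them COX5A at 0.13, with Cy3 saturated on 6 arrays. A saturated Cy3 spot cannot follow the Cy3 level of its array. The slopes of SDH1, SDH3 and COX5A are therefore uncertain as rates. Of 69 amino acid biosynthesis genes 10 fell and 1 rose, with ASN1 and ARG3 at -0.11 and -0.14. In the polymerase I and III list 2 of 21 fell, RPC40 and RPO31. Adjusted over the list alone, 14 tricarboxylic acid cycle genes rose and 1 fell, 19 oxidative phosphorylation genes rose, and 15 amino acid genes fell and 3 rose. INO1 rose by 0.14 ± 0.04. ADH2 at 0.08, PCK1 at 0.02, PHO84 at -0.03, GAP1 at 0.02 and CLN2 at -0.03 did not pass; Cy3 was saturated on 6 arrays for ADH2 and all 8 for PCK1, and Cy5 on 4 for GAP1. HXT7 and MET17 were saturated in Cy5 on all 8 arrays and have no slope to give.

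Camera called 18 of the 35 lists over time as recorded (8 up, 10 down), 23 on the 6 arrays (11 up, 12 down) and 24 with the files exchanged (11 up, 13 down). With an estimated correlation it called 0 in each, with smallest adjusted p-values of 0.57, 0.14 and 0.13. For stress, iron and ribosome biogenesis on the 6 arrays these adjusted p-values were 0.15, 0.14 and 0.15. As recorded, the median slopes of these lists were 0.06, 0.08 and -0.03 per h. With the slide as a block, 21 lists were called as recorded, 22 on the 6 arrays and 24 with the files exchanged. As recorded, slide 1 alone gave 19 and slide 2 alone 22. As recorded, leaving out the 16 h array left 7 called lists and leaving out the 17 h array left 10.

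**Figure D3:**
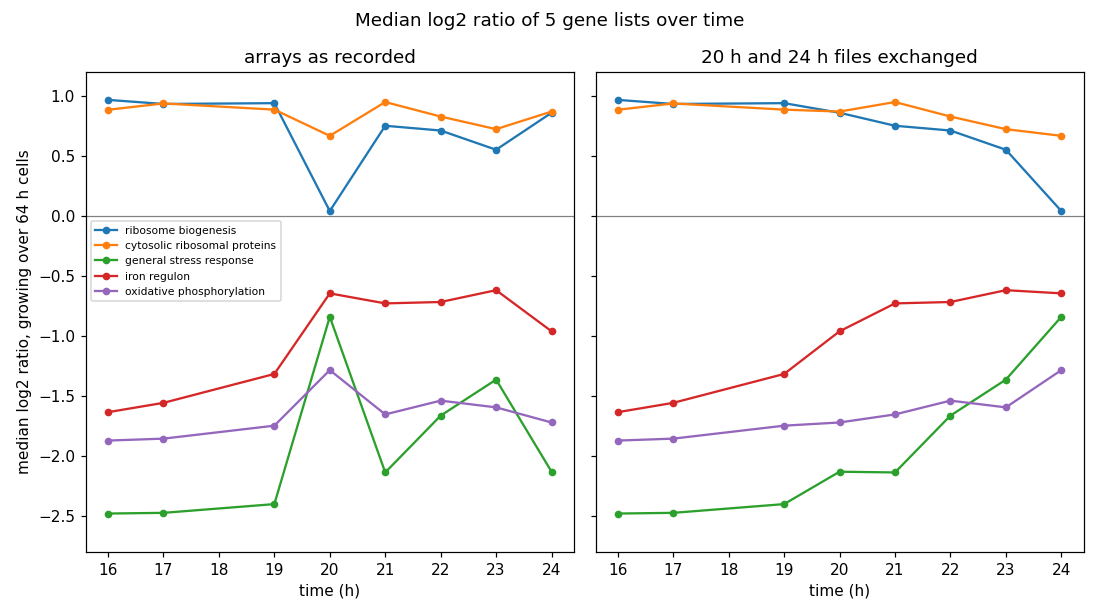
Median log2 ratio of growing over 64 h cells for 5 gene lists (vertical axis) against time in h (horizontal axis), with the arrays as recorded (left) and with the 20 h and 24 h files exchanged (right). Each point is the list's median on 1 array; the ribosome biogenesis median of 0.04 stands at 20 h on the left and at 24 h on the right.

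The last comparison asked whether genes turned within the 8 h. As recorded, limma called 0 genes with a curved course, 395 had an unadjusted p under 0.05, and the smallest adjusted p was 0.19, for the iron oxidase gene FET3. The next 4 were CSS1, SIT1, GPD2 and GRX4, each with an adjusted p of 0.53; CSS1 was saturated in Cy5 on 5 arrays and in Cy3 on 3. On the 6 undisputed arrays 0 genes were called, 260 having an unadjusted p under 0.05. With the files exchanged 37 were called, and 409 with the slide as a block as well. Of 100 orders of the arrays, 5 reached 37, up to 893, so chance is not excluded for the 37. HXT3 curved downward and MRK1, MAL12, USV1 and INO1 upward, with adjusted p-values of 0.0023, 0.0023, 0.019, 0.019 and 0.019. MAL12 was well above background in Cy5 on 7 of 8 arrays. HXT3 was saturated in Cy5 on 3 arrays, which leaves the shape of its course uncertain.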

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

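All tests in this part were chosen after the results were seen, except the counts over rearranged arrays at the recorded times and the comparison of each array with the others. Counts over rearranged arrays for the 6 arrays and the exchanged files belong to fits added after the mismatch was seen. In that comparison 41 measures were examined and 4 stood out; chance gives about 1 in 20. The array recorded at 16 h had 84.1% of its spots well above background in Cy5, against 89.0% to 91.6% on the others. The array recorded at 23 h had 91.1% in Cy3, against 89.5% to 90.2%. On the array recorded at 20 h the ribosome biogenesis genes had a median log2 ratio of 0.0403, against 0.55 to 0.97 elsewhere. There the polymerase I and III genes had a median of -0.00355, against 0.57 to 0.95.

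The arrays recorded at 20 h and 24 h stood out of the order of the rest. If the cells of these samples had departed from the trend, the authors' table would show the same departure, but the higher of the 2 correlations between file and own column was -0.38. With the table as deposited, that argues against such a departure as the cause. An exchange of the scanner files between the samples may account for it: the lower of the crosswise correlations was 0.92. An exchange of the table columns instead stays open. The trend of the other 6 arrays placed the file recorded at 20 h later than the one recorded at 24 h by 6.23 h, with errors of up to 1.21 h on arrays left out in turn, but this assumes a course that does not turn back.

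The time slopes of the added fits could come from a difference between the slides. With the slide as a block, 1079 of the 1079 calls of the exchanged fit and 473 of the 473 calls on the 6 arrays were kept in the same direction. Each slide held early and late arrays, so the block could change the slopes little (r = 0.996 and 0.990 across genes). That outcome was thus likely in advance. It is the layout, more than the count, that argues against a slide difference. Within slide 2 alone, 3 arrays gave 1 call.

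Slopes leaned toward the 64 h state: of the 473 genes called on the 6 arrays, 392 moved toward it and 81 away. Drift in the reference channel is argued against for single genes: on the 6 arrays Cy3 alone called 3 genes and Cy5 alone 385. The median absolute slope there was 0.011 per h in Cy3 and 0.027 in Cy5. As recorded, camera called 4 lists downward and 0 upward from Cy3 alone, and 20 lists from Cy5 alone. Lists were not tested by channel on the 6 arrays, so a small drift shared by many genes stays open. A shrinking of all ratios by 1 common factor was also examined. Of the 23 lists called against 64 h, 12 had slopes beyond 2 jackknife SE of such a factor in both added fits. Their directions were the same in both. Chance gives about 2.3 for 1 fit if the lists are independent. These lists share arrays, as do the fits, and lists with large mean ratios weigh most in the factor. The 12 therefore cannot be weighed against chance. On the 6 arrays the iron regulon medians had a mean of -1.10 and rose by 0.16 ± 0.02 per h. The thiamine and vitamin B6 medians, with a mean of -1.11, had a slope of 0.00 ± 0.01. Camera called the thiamine list downward there, away from the 64 h state, at the preset correlation (adjusted p = 0.041). With an estimated correlation it did not (adjusted p = 0.22). Like means with unlike slopes argue against 1 factor as the whole cause for these 2 lists, picked from the 23. A common factor for part of the slopes stays open. A biological approach to stationary phase was not tested.

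Rearranged arrays tell how far chance accounts for the counts. With the 6 arrays, 2 of 100 orders gave at least 473 calls, the highest other giving 502, and with the files exchanged 2 of 100 gave at least 1079, the highest other giving 1274; chance can be excluded at 0.05 for both, but only given the arrays and times of these fits, which were chosen after the 2 arrays were seen out of order. A count of 0 is reached by any order, so for the recorded times these counts say nothing about chance: 100 of 100 orders for slopes, up to 15 calls, 100 of 100 for curvature, up to 717, and 35 of 35 splits into 4 later and 4 earlier arrays, up to 44. For curvature with the files exchanged, 5 of 100 orders reached 37, up to 893, so chance is not excluded. Orders with many times the real count point to a structure of the arrays, and which one was not tested. The split with 44 calls is that of the exchanged assignment. It was alone in reaching 44, 1 of 35, with 43 the highest other. By rank alone that excludes chance at 0.05 only given that assignment, chosen in the same way. The near tie shows that another grouping of the arrays gave almost as many calls, so the count hardly sets this split apart.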

How the results depend on the processing

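The alternatives that exchange the 20 h and 24 h files or leave them out were chosen after seeing the data; all others were chosen before. For each effect the cause was not tested unless stated. The count of genes changing with time, 0 as recorded, was 1921 from the authors' value table, whose 20 h and 24 h columns match the other file, 1079 with the files exchanged, 1707 with the slide as a block as well, 473 on the 6 undisputed arrays and 1187 there with the slide block. It stayed at 0 under every other alternative, each array left out included. Genes with a curved course, 0 as recorded, numbered 307 from the table, 37 with the files exchanged and 409 with the slide block as well, and 0 to 1 without single arrays. Genes differing from the 64 h reference, 4686, fell to 2746 on slide 2 alone, which has 3 arrays, and to 838 with a limit of 2-fold, and ranged from 4490 to 4785 without single arrays. Gene lists that shift with time, 18 as recorded, numbered 7 for 4 later against 4 earlier arrays, 4 from Cy3 alone and 0 with an estimated correlation, and 7 to 23 without single arrays. Gene lists that differ from the 64 h reference, 23, numbered 0 with an estimated correlation and 23 to 25 without single arrays. In 4 later against 4 earlier arrays, ribosome biogenesis (0.0123) and RNA polymerase I and III (0.0296) changed sign. These 2 values are log2 differences between the sets of arrays, not slopes per h, and neither passed (camera adjusted p = 0.89). The earlier set held the array recorded at 20 h. The list glycolysis and fermentation, uncalled as recorded, was called the other way with the scanner's ratios (-0.0324), median centring only (-0.0185) and the table (-0.0335), and against 64 h with median centring (0.50). The log2 ratio computed for MET17 turned to 0.26 with median centring, but both channels were saturated on all 8 arrays, so it says nothing about the gene. A change of sign between values that both miss the threshold was not counted as a turn. With spots above background in both channels on all arrays, 5187 genes were tested and 4316 called against 64 h. That filter leaves out the dim genes, YRO2, STL1, GNP1 and HXT1 among them, so it does not test their calls.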

Other observations

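The test of time slopes in this part was added after the data were seen; the lists were chosen before. Against the 64 h cells, biotin genes were lower in growing cells in 5 of 5 cases, with a median log2 ratio of -4.03 (adjusted p = 0.36 with an estimated correlation). Of 26 iron regulon genes 23 were lower and 1 higher, with a median of -1.22 (adjusted p = 0.38 with an estimated correlation). Of 24 genes of the heat shock factor chaperone list 19 were lower and 4 higher, with a median of -0.80 (adjusted p = 0.12 with an estimated correlation). Aminoacyl-tRNA synthetase genes were higher in 19 of 20 cases and lower in 1, with a median of 0.55 (adjusted p = 0.37 with an estimated correlation). Mating and haploid-specific genes were lower in 17 of 25 cases and higher in 5 (adjusted p = 0.30 with an estimated correlation).

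Over time on the 6 undisputed arrays, histone genes had a median slope of 0.05 per h, with 2 of 10 rising and 5 when adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Of 26 nitrogen catabolite repression genes 7 fell and 2 rose (adjusted p = 0.15 with an estimated correlation). As recorded, 0 members of either list passed over all genes. Thiamine and vitamin B6 genes, lower in growing cells by a median of -1.11, had a median slope of -0.01 per h, with 2 of 21 falling. Camera called the list downward at the preset correlation (adjusted p = 0.041), but not with an estimated one (adjusted p = 0.22).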
